A study of Sus scrofa with 4 samples.

How the data were processed

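Gene expression was measured in porcine (Sus scrofa) blastocysts on 4 two-colour oligonucleotide arrays. Each array held 2 samples, a pool of blastocysts grown from cumulus-oocyte complexes (the oocyte with the cumulus cells around it) matured in coculture with porcine luteal cells, and a pool from complexes matured without them, the control. Per the labels, there were 4 pools, each of 10 blastocysts, from days 7 and 8; which pool came from which day, and whether the 4 pools are counted per condition, is not given in the sources used here. The arrays are named as biological replicates 1 to 4 in the labels. On replicates 1 and 2 the coculture RNA carried Cy5 and the control RNA Cy3, and on replicates 3 and 4 the dyes were exchanged. Nothing in the labels says how the pools relate to donors, in vitro fertilisation runs or culture batches. The p-values therefore measure only the spread between pairs of pools that share a dye assignment.

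Per the labels' protocols, RNA was extracted with a kit that separates DNA and RNA, amplified, and labelled chemically by the Universal Linkage System, which binds a dye to guanine without an enzyme. The deposited scanner tables hold, per spot and dye, the raw median and mean pixel intensity and the local background intensity on a linear scale that ends at 65535, with a mark on spots left out by the image quantification; the scanner and the quantification software are not given in the sources used here. The authors also deposited a table of log2 values, 1 column per array. Per the submitters' processing notes, limma was used, with no version given. That table was set against the scanner values. Its columns were log2 ratios of Cy5 over Cy3 on every array, not turned for the dye exchange, and followed plain background subtraction, loess and quantile normalization of the median intensities with correlations of 0.968 to 0.981 across probes, slopes of 1.02 to 1.04 and median absolute differences of 0.0038 to 0.0049. The medians of its columns were -0.0133, -0.013, -0.000395 and -0.0167 for replicates 1 to 4. Its scale and direction were settled by this comparison, and its exact centring stays unknown.

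The median pixel intensities were corrected for background with normexp (offset 50) over all spots and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 (R 4.3.3). Spots marked as left out (74 to 150 per array) had no value; saturated spots were kept. Each of the 43794 probes had 1 spot. Log2 ratios of Cy5 over Cy3 were fitted with lmFit and eBayes, with an intercept that takes up the dye effect of each probe and a coculture term of opposite sign in the 2 dye orientations, which leaves 2 residual degrees of freedom. The intercept also takes up any other difference between the orientations, so the error is the spread within them. In eBayes, the spread over all tested probes added 5.92 prior degrees of freedom. Ratios are given as coculture over control. A probe was above the detection limit of a channel if its intensity exceeded the mean plus 2 SD of the 153 negative-control spots in that channel. Probes were tested if they exceeded the limit on at least 2 arrays in the channel of at least 1 condition and had a value on at least 3 arrays. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05.

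Gene symbols came from the platform's annotation as supplied for the authors' table, updated through RefSeq annotation of assembly Sscrofa11.1, which was used for names only. Of the 43794 probes, 18121 had 1 symbol and none had several; the others are unnamed here, which does not mean that they lack a gene. Of the 18121, 17329 carried a symbol current in RefSeq, 447 were matched by accession, 344 by synonym and 1 by a list of old symbols. A gene with several probes was represented by the probe of highest mean intensity. Before the data were examined, 28 gene lists were fixed, including markers of other cell types. The 24 lists with at least 5 genes tested were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with limma's fry beside it. The genes named were also chosen by a rule fixed before the data were examined: up to 12 per direction with adjusted p under 0.05 and 1 sign on all 4 arrays, places left being filled with the genes of smallest unadjusted p and 1 sign on all 4 arrays; the 2 genes of smallest unadjusted p from each list (4 for a list that passed); and a fixed set of markers. For genes above the detection limit on no array of 1 condition, a lower bound of the fold of mean signals was computed. Channel values after loess and Aquantile normalization were used. The mean of the brighter condition was set against a floored mean of the other. Its value per array was the higher of the lowest signal among detected probes and the probe's own signal. Where the probe's own signal was the higher on every array, the bound equals the measured fold and is no minimum. The bound concerns the dim signal only and leaves out the spread between arrays.

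The fit was tested on simulated data with the dye effects and error spread of the coculture against control fit over 15651 probes, 200 of them changed. It recovered 66% of 50 probes changed 2-fold, 98% of 50 changed 3-fold, and all 50 at each of 4-fold and 8-fold, while 14 of the 196 probes called were unchanged ones. In simulated data over the genes of the list test, camera called a list of 36 genes shifted by 0.5 on the log2 scale and no other list. The simulated errors were independent between genes. The recovery of probes holds for 200 changed at once, since the adjustment of p-values is looser when many probes change. It does not give the recovery of a few 2-fold changes.

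Alternatives were no background correction, plain subtraction, normexp without an offset, median centring, Aquantile and scale normalization after loess, a fit without the dye term, a separate-channel fit, no filter and a stricter filter on dim probes, trended and robust variance, array weights, the mean over the probes of a gene, the authors' table, other thresholds, other list tests and leaving out each array. Mean pixel intensity and the arrays of each dye orientation alone were added after seeing the data, and fry's test for change in either direction was taken up then too.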

Results

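The comparison asked how maturation of the cumulus-oocyte complex together with luteal cells, the progesterone-secreting cells of the corpus luteum, is reflected in the transcripts of the blastocysts that develop afterwards. It rests on 4 arrays, each carrying 1 pool per condition. Median probe intensities were 630 to 840 in Cy3 and 585 to 798 in Cy5, over median local backgrounds of 84 to 110 and 118 to 156. The negative-control spots had medians of 596 to 787 in Cy3 and 591 to 817 in Cy5, close to those of the probes in Cy3 and above them in Cy5 on each array, so that much of the probe signal lay at the level of unspecific hybridisation. In the control channel 29.9% to 34.9% of the probes exceeded the detection limit, and in the coculture channel 23.5% to 29.3%. The control share lay above the coculture share on each of the 4 arrays. Loess centres the ratios of each array, so a difference shared by most probes would not show in them. The number of arrays limits the precision: the 95% interval of a log2 ratio reached a median of 0.363 to either side.

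No gene differed between coculture and control blastocysts beyond the spread between pairs of pools within a dye orientation. No gene list shifted to 1 side beyond it. The lowest named ratios with 1 sign on all 4 arrays belonged to NPPB, APOE, CTSZ and GRN. NPPB, which encodes B-type natriuretic peptide, had a log2 ratio of -1.05 (95% interval -1.43 to -0.68). APOE, a lipid-carrying apolipoprotein, stood at -1.03 (-1.44 to -0.62). CTSZ, a lysosomal protease, stood at -0.998 (-1.44 to -0.56), and GRN, which encodes progranulin, at -0.99 (-1.39 to -0.59). The highest were NEFL, the neurofilament light chain, at 0.86 (0.53 to 1.20) and AKAP9, a scaffold of protein kinase A at the centrosome and Golgi, at 0.67 (0.34 to 1.00), or 0.38 without background correction and 0.228 with mean pixel intensities. Each of these had a limma adjusted p of 0.633 and did not pass. Of the 15651 probes tested, 7308 with a symbol representing 5359 genes, limma called 0 at an adjusted p under 0.05 and 0 at an adjusted p under 0.10. At an unadjusted p under 0.05 there were 1224 probes, 7.82% of those tested, with 648 higher and 576 lower in coculture, and 291 of them also differed by at least 1.5-fold, 155 higher and 136 lower. The fits on background, normalization, filter and variance alternatives, the separate-channel fit and the authors' table also gave 0 probes at an adjusted p under 0.05, while replicates 1 and 2 alone, taken after seeing the data, gave 2. The unadjusted count was 608 without replicate 2 and 814 without the dye term.

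The other genes of smallest p and positive ratio did not pass either. TLR7, an endosomal receptor for single-stranded RNA, stood at 0.61 (95% interval 0.24 to 0.97), and CXCR4, the receptor of the chemokine CXCL12, at 0.55 (0.18 to 0.92). EFCAB2 stood at 0.63, CPNE5, a calcium-dependent membrane-binding protein, at 0.60, DLC1 at 0.56, BCAS2, a spliceosome component, at 0.53, RAB27A, a GTPase of vesicle secretion, at 0.51, ANGEL2 at 0.49, and WDR62, a centrosomal protein, and PARP12, an ADP-ribosyltransferase, at 0.48 each. With mean pixel intensities in place of medians, ratios were cut by over 1.5 times for 8 of the 24 genes of smallest p: AKAP9, EFCAB2 (0.386), CPNE5 (-0.00926), BCAS2 (0.245), WDR62 (0.197), PARP12 (0.0332), PPP1R12C (-0.424) and BMP7 (-0.468). Without background correction they were for 10: NEFL, AKAP9, CPNE5, WDR62 (0.272), PARP12, NPPB (-0.677), HTT (-0.558), BTBD2 (-0.414), BMP7 and PMEPA1 (-0.419). WDR62 had ratios of 0.045 and 0.055 on replicates 1 and 2 and of 0.86 and 0.97 on replicates 3 and 4. NEFL, CPNE5 and PARP12 were above the detection limit on no control array, each with a limma adjusted p of 0.633. The lower bound from mean signals, coculture over control, was 1.68-fold for NEFL, 1.52-fold for CPNE5 and 1.36-fold for PARP12. That of CPNE5 equals its fitted fold and is not a minimum. The bounds leave out the spread between arrays: the 95% intervals of the fold began at 1.45, 1.17 and 1.11. The bounds also hold only for the background correction used. Without it the log2 ratios were 0.44 for NEFL, 0.27 for CPNE5 and 0.23 for PARP12, folds of 1.35, 1.20 and 1.17. NEFL stood at 0.51 in the authors' table.

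The other genes of smallest p and negative ratio did not pass either. BMP7, a secreted ligand of the transforming growth factor family, stood at -0.74 (95% interval -1.11 to -0.37) and PMEPA1, a membrane protein that inhibits signalling by that family, at -0.63 (-0.95 to -0.30). BMP7 was above the limit on 3 control arrays and on no coculture array, with a limma adjusted p of 0.633. Its bound from mean signals was 1.67-fold lower in coculture. This equals the fitted fold, so it is not a minimum, and it leaves out the spread between arrays. The 95% interval of the ratio of BMP7, coculture over control, ran from 0.462 to 0.776. Without background correction the fold was 1.30. CD151, a tetraspanin that binds integrins, stood at -0.99, LMF2 at -0.93, PRAP1 at -0.86, HTT, the huntingtin gene, at -0.85, BTBD2 at -0.77 and PPP1R12C, a regulatory subunit of myosin phosphatase, at -0.67. Other probes of some of these genes pointed the opposite way: the other probe of LMF2, 1 of 2 for PRAP1 and 1 of 3 for HTT. The other probe of APOE stood at -0.0017 (95% interval -0.37 to 0.37), and the other probes of CTSZ stood at -0.57 and -0.26. The mean over the probes of a gene cut the ratio by over 1.5 times for 6 of the 24: HTT (-0.213), PRAP1 (-0.391), LMF2 (-0.41), APOE (-0.516), CTSZ (-0.608) and RAB27A (0.318).

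**Figure D1:**
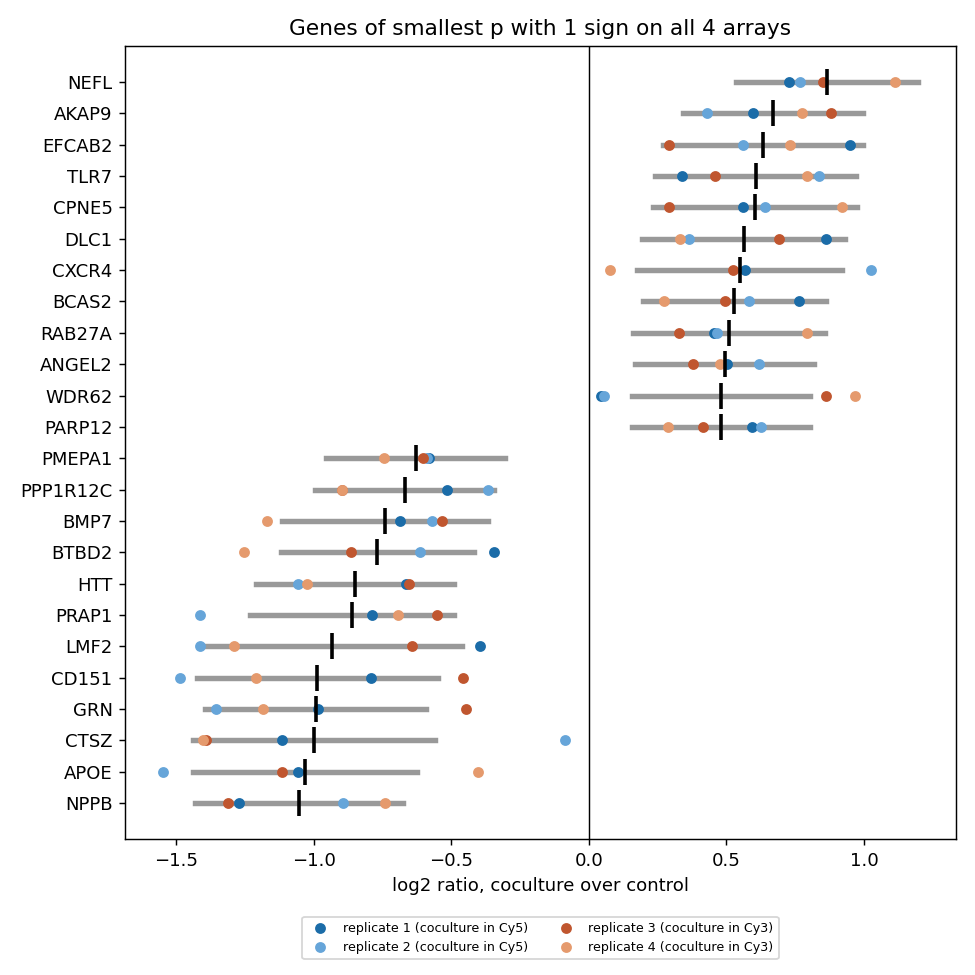
Log2 ratio of coculture over control (x axis) for the 24 genes (y axis) of smallest unadjusted p with 1 sign on all 4 arrays. Dots are single arrays, blue with coculture in Cy5 and orange with coculture in Cy3, the black bar is the fitted ratio and the grey bar its 95% interval. The fitted ratios run from -1.05 for NPPB to 0.86 for NEFL, and none of the 24 passed an adjusted p of 0.05.

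None of the 24 gene lists passed limma's camera test, and 2 had an unadjusted p under 0.05. With an estimated correlation 0 lists passed, and 0 passed fry's test of a shift in 1 direction. The trophectoderm markers, genes of the outer epithelium of the blastocyst, had a median log2 ratio of -0.18, with 9 of 12 genes below 0 and list medians of -0.10, -0.15, -0.18 and -0.15 on replicates 1 to 4 (camera unadjusted p = 0.012, adjusted p = 0.28; unadjusted p = 0.12 with an estimated correlation). No trophectoderm gene passed over all probes or adjusted over the list alone. GATA2 stood at -0.48 and TEAD4 at -0.45, or at -0.31 and -0.16 without replicate 2, CDX2 at -0.19 (95% interval -0.52 to 0.14) and GATA3 at -0.14 (-0.56 to 0.28), all 4 being transcription factors of this lineage. TEAD4 was above 0 on replicate 1 and GATA3 too, while GATA2 and the brightest probe of CDX2 were below 0 on all 4 arrays. The other probes of CDX2 stood at -0.25 and 0.15, and neither was below 0 on all 4.

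The primitive endoderm markers, genes of the layer that lines the blastocyst cavity, had a median of -0.28 over 7 genes, with medians of -0.30 and -0.38 on replicates 1 and 2 and of 0.32 and 0.30 on replicates 3 and 4 (limma's camera, unadjusted p = 0.032, adjusted p = 0.38; unadjusted p = 0.20 with an estimated correlation). Adjusted over the list alone, 2 genes passed, APOA1 and APOE, the latter by 1 of its 2 probes, and over all probes 0 did. APOA1, the main protein of high-density lipoprotein, had a fitted ratio of -1.08 that came from replicates 1 and 2, at -2.15 and -2.54, against -0.029 and 0.39 on replicates 3 and 4. GATA6, a transcription factor of the lineage, stood at 0.34 (95% interval -0.07 to 0.74). The inner cell mass and epiblast markers, genes of the pluripotent cells, had a median of -0.087, with 5 of 7 below 0 (camera adjusted p = 0.95). POU5F1, which encodes the pluripotency factor OCT4, stood at -0.38 (-0.73 to -0.02), below 0 on 3 of 4 arrays, and its other probe had the same sign. SOX15, above the limit on no control array, stood at 0.37 (95% interval -0.18 to 0.91) and did not pass. Its lower bound from mean signals, which leaves out the spread between arrays, was 1.25-fold higher in coculture. Its array values were -0.24, 0.064, 1.56 and 0.084, and without replicate 3 it stood at -0.00303. Without background correction its fold was 1.12. SOX2 was not tested because it exceeded the limit too seldom, and NANOG had no probe named here.

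Markers of the maternal cells that surround or accompany the oocyte were dim. Of the 8 tested genes of granulosa, cumulus and luteal cells, 0 exceeded the limit in both channels of all 4 arrays; their median was 0.035, with 4 above and 4 below 0 (limma's camera, adjusted p = 0.95). STAR, which carries cholesterol into mitochondria for steroid synthesis, stood at 0.085 (95% interval -0.31 to 0.48), AMH at 0.21 and SHAS2, the hyaluronan synthase gene HAS2, at 0.23. HSD3B1 was not tested, and CYP11A1 had no probe named here. The oocyte and maternal transcripts had a median of 0.026 with 6 of 12 above 0 (adjusted p = 0.96); MOS stood at -0.38, ZAR1L at 0.30 and GDF9 at 0.059, while BMP15 exceeded the limit on no array. Of markers of fibroblasts and stroma, 4 of 5 lay above 0 with a median of 0.18 (adjusted p = 0.52), TAGLN at 0.55, or 0.23 without replicate 2, and DCN at -0.37, with means of 0.25 on replicates 1 and 2 and -0.99 on replicates 3 and 4. Lists of endothelial cells, leukocytes and sperm had 3 tested genes each and were not tested as lists, with medians of 0.15, 0.19 and 0.087. EGFL7 stood at -0.41 and VWF at 0.28, AIF1 at 0.31 and CD79A at 0.19, SPACA1 at 0.15, and SPATA18 at -0.60, the 1 gene of the sperm list to pass when adjusted over the list alone. Its array values were -0.035 and 0.23 on replicates 1 and 2 and -1.06 and -1.55 on replicates 3 and 4. SPATA18 is also expressed outside the testis, as a regulator of mitochondrial quality. Of the sex chromosome markers 1 was tested, EIF1AY, at 0.15; XIST had no probe named here.

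Stress and metabolism lists had medians within 0.11 of 0 and adjusted camera p-values (limma) of at least 0.45. In the heat shock and unfolded protein response list, 16 of 24 genes lay below 0 with a median of -0.039 and a mean of -0.12 (adjusted p = 0.45). HSPB1, a small heat shock protein, stood at -0.96 with array values from -2.39 to 0.22, and PDIA3, a disulfide isomerase of the endoplasmic reticulum, at -0.53. Antioxidant defence had a median of -0.055, 13 of 22 genes lying below 0 (adjusted p = 0.93), with GSS at 0.46 and GPX1 at -0.84, which came from replicates 2 and 3 at -1.68 and -1.56, against -0.12 and -0.013 on replicates 1 and 4. Apoptosis genes had a median of -0.078, 10 of 14 below 0 (adjusted p = 0.58), with ENDOG at -0.36 and CYCS at -0.34. Glycolysis and glucose uptake had a median of -0.094, 8 of 13 below 0 and a list median below 0 on all 4 arrays (adjusted p = 0.52). LDHA, lactate dehydrogenase A, stood at -0.47 (95% interval -0.81 to -0.14) and PDHA1, of the pyruvate dehydrogenase complex, at 0.39.

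Oxidative phosphorylation genes had a median of 0.0097 with 20 of 36 above 0 (limma's camera, adjusted p = 0.52). This was the 1 list of 24 to pass fry's test for change in either direction (limma, adjusted p = 0.0056), a test that does not compare the list with other genes. The adjusted p of the list in that test was 0.57, 0.46, 0.41 and 0.22 without replicates 1, 2, 3 and 4, 0.83 with median centring, 0.51 without the dye term and 0.13 with the authors' table. UQCRB stood at 0.37 and above 0 on all 4 arrays, and NDUFS6 at -0.55. Cholesterol biosynthesis had a median of -0.029 over 11 genes (adjusted p = 0.99), with HMGCS1 at 0.19 and INSIG1 at -0.29 by its brighter probe. Fatty acid and lipid droplet metabolism had a median of -0.028 and a mean of 0.018 over 23 genes (adjusted p = 0.99), with PNPLA2, adipose triglyceride lipase, at -0.50 and FABP5, a fatty acid carrier, at 0.99, whose array values ran from -0.38 to 2.34. Steroid synthesis and steroid receptors had a median of -0.11 over 15 genes (adjusted p = 0.96), with PAQR7, a membrane progestin receptor, at 0.44 and above 0 on all 4 arrays, and STARD3 at -0.40.

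Lists of blastocyst function and regulation did not pass either. Blastocoel formation and cell junctions had a median of -0.068 with 12 of 18 below 0 (limma's camera, adjusted p = 0.46). Its list medians lay below 0 on all 4 arrays. The tight junction genes TJP3 and OCLN stood at -0.59 (95% interval -0.98 to -0.21) and -0.45 (-0.80 to -0.10). With mean pixel intensities they stood at -0.323 and -0.222. The other probe of OCLN stood at -0.094 (95% interval -0.45 to 0.26), and the mean over its probes at -0.271. Maternal recognition and implantation had a median of -0.012 and a mean of 0.0092 over 17 genes (adjusted p = 0.95), with FGFR2 at 0.41 and LGALS3 at -0.29. DNA methylation and chromatin enzymes had a median of -0.015 and a mean of 0.024 over 23 genes (adjusted p = 0.96), with SIRT1 at 0.47, from -0.23 and -0.26 on replicates 1 and 2 and 1.48 and 0.88 on replicates 3 and 4. TET2, above the limit on no control array, stood at 0.68 (95% interval 0.02 to 1.34) and did not pass. Its lower bound from mean signals over all 4 arrays, which leaves out their spread, was 1.52-fold higher in coculture. Its array values were 0.51, 0.29, 1.95 and -0.022, and without replicate 3 it stood at 0.19. Without background correction its fold was 1.38. Imprinted genes had a median of -0.038 over 8 genes (adjusted p = 0.93), with DIRAS3 at -0.78, or -0.29 without replicate 1, and GNAS at -0.29. Interferon response genes had a median of 0.038 over 12 genes (adjusted p = 0.96), with IRF7 at -0.52 and OASL at 0.55. Hypoxia response had a median of 0.067 over 13 genes (adjusted p = 0.52), with LOX at 0.48 and ARNT at 0.34.

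Of the housekeeping and growth lists, cell cycle and DNA replication had a median of 0.10 with 18 of 27 genes above 0 (limma's camera, adjusted p = 0.46), E2F1 standing at 0.65, or 0.38 without replicate 3, and CDT1 at -0.61, or -0.20 without replicate 2. Cytosolic ribosomal proteins had a median of 0.027 with 29 of 45 above 0 (adjusted p = 0.93), with RPL27 at 0.24 and RPL30 at -0.21. Proteasome genes had a median of -0.022 over 23 genes (adjusted p = 0.96), with PSME1 at -0.30 and PSMC6 at -0.25. Among the genes named for their lists, another probe pointed the opposite way for TEAD4, CDX2, STARD3, FGFR2, DIRAS3, GNAS, CDT1, RPL30, PSMC6 and ARNT. The genes often used as references in quantitative PCR had a median of 0.068 over 13 genes (adjusted p = 0.96), with GAPDH at -0.26 and TUBB at -0.24.

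**Figure D2:**
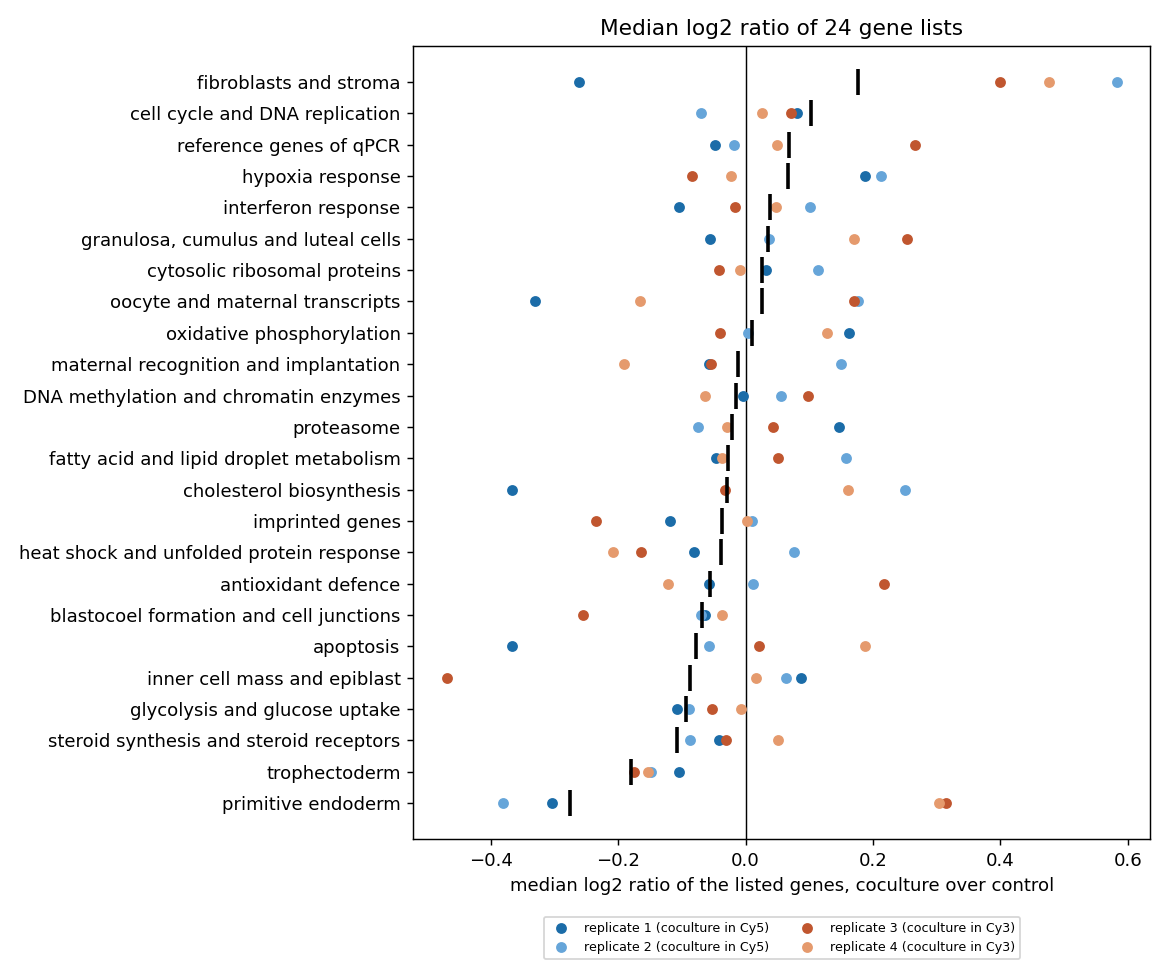
Median log2 ratio of coculture over control (x axis) for the 24 tested gene lists (y axis). Dots are the median over a list's genes on each array, blue with coculture in Cy5 and orange with coculture in Cy3, and the black bar is the median of the fitted ratios, which need not lie between the dots. Trophectoderm lies below 0 on all 4 arrays, and primitive endoderm lies below 0 on replicates 1 and 2 and above 0 on replicates 3 and 4.

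Ratios of coculture over control did not go together across probes between arrays of opposite dyes. Of the 83 genes named, 16 had means of opposite sign in the 2 dye orientations: APOA1, SPATA18, SIRT1, SOX15, E2F1, FGFR2, ZAR1L, CD79A, DCN, EGFL7, LGALS3, PSMC6, SHAS2, EIF1AY, GDF9 and GATA3. Leaving out 1 array moved the ratio by over 1.5 times for 36 of the 83: GATA2, TEAD4, SOX15, SHAS2, ZAR1L, EGFL7, VWF, TAGLN, SPACA1, ENDOG, CYCS, GPX1, HSPB1, PDHA1, NDUFS6, INSIG1, HMGCS1, FABP5, LGALS3, TET2, DIRAS3, GNAS, E2F1, CDT1, RPL27, PSME1, PSMC6, LOX, ARNT, EIF1AY, TUBB, GAPDH, GDF9, GATA3, GATA6 and STAR. Turned to coculture over control, replicates 1 and 2 correlated at 0.205 and replicates 3 and 4 at 0.164 over 15552 probes, which are not independent of each other. The 4 pairs of arrays with opposite dyes correlated at -0.056, -0.191, -0.0489 and -0.0266. One sign on all 4 arrays was found for 2059 probes, 13.2%, with 983 higher and 1076 lower. Independent arrays would give 12.5%. The correlations show that the arrays were not independent, so 12.5% need not be the share without a coculture effect. The dye term of limma's fit had 0 probes at an adjusted p under 0.05, with a smallest adjusted p of 0.174, and 1817 at an unadjusted p under 0.05.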

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

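Of 113 values examined for 1 array standing apart from the other 3, 5 were found, and chance gives about 1 in 20, here 5.65. The tests of dye bias, of the APOA1 probe and of the count past the threshold under other splits were chosen only after the result was seen.

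PMEPA1 had a log2 ratio of -0.743 on replicate 4 against -0.58 to -0.60 on the others. CDX2 stood at -0.3611 on replicate 3 against -0.12 to -0.15 elsewhere. The inner cell mass and epiblast list had a median of -0.469 on replicate 3, against 0.016 to 0.088. The list of blastocoel formation and cell junctions had a median of -0.255 on the same array, against -0.037 to -0.070. The endothelial list, of 3 genes, had a median of 0.425 on replicate 1, against -0.040 to 0.035.

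Other assignments of the channels within arrays were counted, a split and its mirror once, leaving out the one that coincides with the dyes: 7 remain, the real one included. They are too few for a share under 0.05. For probes at an adjusted p under 0.05 in limma the real count was 0, the highest other 19, and 7 of the 7 splits gave at least as many as the real one, as they must with a real count of 0, so this count decides nothing. For probes at an unadjusted p under 0.05 the real count was 1224 and the highest other 1159. Of the 7 splits, 1 gave as many, the real one. The split with 1159 exchanges replicate 4 alone, so the dyes are not balanced in it as they are in the real one. The other balanced splits, exchanging replicates 2 and 3 or 2 and 4, gave 374 and 643. The split with 19 probes exchanges replicates 2 and 4 and so sets the Cy5 over Cy3 ratios of replicates 1 and 4 against those of 2 and 3, which points to a structure of the arrays; it was singled out as the highest of 6 and no cause was tested. The median intensities of replicates 1 and 4 were 758 and 778 in Cy3 against 585 and 631 in Cy5, and those of replicates 2 and 3 were 840 and 630 against 798 and 751. The sources used here do not tie the day of collection to pools.

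Turned to coculture over control, arrays with opposite dyes correlated below 0. A dye effect of each probe lowers these correlations, so they do not show that no coculture ratio was shared. Probe-specific dye bias is a candidate explanation: as scanned, Cy5 over Cy3, the 4 pairs of opposite orientation had a mean correlation of 0.0806, above 0 in all 4. These are the correlations of the turned ratios with the sign changed, so they restate the observation and do not test the explanation. An exchange of dyes not made on replicates 3 and 4, against the labels, would give the same sign. If so, the dye coefficient would hold the condition and different probes of a gene would share it; over 1245 genes the 2 brightest probes correlated at 0.176 in the dye coefficient and 0.302 in the coculture coefficient, a difference of -0.127 with a bootstrap SE of 0.0423. A lower value for the dye had been set in advance to speak against this explanation, but that bound was wrong by design, since without an exchange the coculture coefficient would hold differences between pools, which probes of a gene also share. The share of detected probes goes with the labels: it was higher in the control channel on all 4 arrays, which is Cy3 on replicates 1 and 2 (34% and 34.9%, against 29.3% and 25.7%) and Cy5 on replicates 3 and 4 (34.9% and 29.9%, against 23.5% and 24%). That argues against an exchange not made, but 4 arrays are too few to exclude it, so it stays open.

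APOA1 was low in coculture on replicates 1 and 2 alone, a difference of -2.52 from replicates 3 and 4. A smaller share of endoderm cells in those coculture pools is a biological hypothesis. Over 5 other genes listed for the visceral endoderm, the median difference was -0.385, between the bounds set in advance. It lay at percentile 6.05 of 10000 random lists matched on intensity. Of these, APOC3 differed by -1.69, RBP4 by -0.95, APOA2 by -0.385, CST3 by -0.295 and FABP1 by 0.019. The list was meant for secreted proteins, but that of FABP1 is cytosolic. The median without FABP1, the only gene above 0, was not computed, so the outcome may depend on it. Dye bias of the probe may also account for this difference between orientations, and with 1 tested APOA1 probe no other probe can decide. Alone, it would give ratios of equal size and opposite sign in the 2 orientations. The means were -2.35 and 0.178, and the fitted ratio of -1.08 did not pass. For the difference between orientations the 2 explanations cannot be told apart, because the orientation of the dyes and the pairs of pools coincide.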

How the results depend on the processing

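Mean pixel intensity, the arrays of 1 dye orientation alone and fry's test in either direction were chosen after seeing the data. The signal limits all values, since negative-control spots had medians close to those of the probes, above them in Cy5 on all 4 arrays. Limma gave 0 probes at an adjusted p under 0.05 in all settings run on 3 or 4 arrays; the smallest adjusted p was 0.0952 without replicate 4 and 0.186 in the separate-channel fit. With replicates 1 and 2 only it gave 2 (APOA1 and the unnamed EMPV1_34317), and with replicates 3 and 4 only 0. The threshold of an unadjusted p under 0.05 and 1.5-fold gave 291. At an unadjusted p under 0.05 there were 814 without the dye term, 1898 in the separate-channel fit, 2633 of 43725 without a filter, 642 of 7208 with the stricter filter, and 608 to 1509 when 1 array was left out, the lowest without replicate 2. Camera and fry were not run on 1 orientation alone. Camera gave 0 lists in every setting it was run in, with a smallest adjusted p of 0.062 with the mean over probes and 0.075 without replicate 1. Fry in either direction gave 1 list; it gave 0 with median centring, with scale normalization and with the mean over probes, 2 with the authors' table, and 0 to 1 when 1 array was left out, 0 without replicate 1 or 2. The call on oxidative phosphorylation was also lost where other lists were counted: its adjusted p was 0.51 without the dye term, 1 with mean pixel intensity, 0.13 with the authors' table, 0.41 without replicate 3 and 0.22 without replicate 4. Aquantile normalization leaves log ratios as they are and tests nothing here. A slide as a block was not run, since the files used here name no slide. Each log ratio pairs the 2 pools of an array, so the fit is itself the paired one.

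Of 1543 values of 83 named genes under alternatives, 1530 kept their sign and none passed. Of 452 list medians, 400 kept it. Neither count is a measure of stability, since many values could not change. Aquantile, the fit without the dye term, trended and robust variance and array weights left ratios and list medians as they were. The separate-channel fit and the filters left the ratios as they were. The mean over probes did so for genes with no other tested probe. Genes with the same sign on all arrays could not change it when an array was left out. Ratios were cut by over 1.5 times for 35 of the 83 genes with mean pixel intensity and for 29 without background correction. The cause of the changes of sign was not tested. With mean pixel intensity they were -0.00926 for CPNE5, -0.2 for VWF, -0.00314 for CD79A, 0.00138 for GNAS and 0.0253 for RPL30, and medians of 0.012 for antioxidant defence, 0.014 for steroid synthesis, 0.029 for blastocoel formation and -0.00014 for hypoxia response. With median centring they were -0.0267 for GDF9, -0.035 for granulosa, cumulus and luteal cells, -0.043 for oocyte transcripts, -0.077 for oxidative phosphorylation, -0.044 for ribosomal proteins, -0.026 for interferon response, -0.026 for hypoxia response and -0.003 for reference genes. Without a filter, medians were -0.0088 for granulosa, cumulus and luteal cells, -0.074 for oocyte transcripts and -0.0052 for interferon response. The stricter filter gave 0.044 for maternal recognition, -0.067 for interferon response and 0.0018 for proteasome. The mean over probes gave -0.00044 for granulosa, cumulus and luteal cells and 0.028 for chromatin enzymes. The authors' table gave -0.019 for oxidative phosphorylation, 0.012 for maternal recognition, 0.0066 for chromatin enzymes and -0.028 for ribosomal proteins. Maternal recognition stood at 0.0013 without background correction, 0.0015 with subtraction and 0.065 with scale normalization, and chromatin enzymes at 0.0078 without background correction and 0.0043 with scale normalization.

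Leaving out 1 array gave ranges across 0 for GDF9 (-0.0732 to 0.191), GATA3 (-0.307 to 0.0262), STAR (-0.11 to 0.279), SOX15 (-0.00303 to 0.734) and SHAS2 (-0.0415 to 0.51). List medians did so for chromatin enzymes (-0.045 to 0.042), antioxidant defence (-0.13 to 0.04), cholesterol biosynthesis (-0.19 to 0.11), ribosomal proteins (-0.0013 to 0.048), lipid metabolism (-0.018 to 0.046), glycolysis (-0.12 to 0.003), granulosa, cumulus and luteal cells (-0.075 to 0.088), interferon response (-0.046 to 0.05), maternal recognition (-0.024 to 0.062), oocyte transcripts (-0.11 to 0.11), oxidative phosphorylation (-0.018 to 0.099), proteasome (-0.061 to 0.083), reference genes (-0.025 to 0.11) and steroid synthesis (-0.1 to 0.0062).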

Other observations

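The hypotheses on lysosomal and growth factor target genes were formed from the ranking of single genes and tested on other genes of the same arrays, with the tests written before those genes were examined, except the tests of a fall as large as that of the 2 genes, which were chosen after. The probes named by their number or as second probes were chosen after their values were seen.

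The smallest unadjusted p of all probes belonged to EMPV1_18268, which is unnamed here: its log2 ratio was 1.04, with 0.98, 0.795, 1.29 and 1.11 on replicates 1 to 4 and a limma adjusted p of 0.633. A second probe of INSIG1, a sterol-regulated membrane protein that restrains cholesterol synthesis, stood at -0.94, below 0 on all 4 arrays, against -0.29 for the brighter probe, and did not pass either.

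GRN and CTSZ, whose proteins reach lysosomes, were among the lowest ratios, so lysosomal genes might be lower in coculture. The other 23 lysosomal genes tested had a median log2 ratio of 0.016, with 10 below 0, and limma's camera gave an unadjusted p of 0.73, so the test found no shift of the group. The 21 of them above the detection limit in both channels of all arrays had a median of 0.0163 with an SD of 0.228, and the lowest stood at -0.553. The intervals of GRN and CTSZ end at -0.558 or lower. The values of the 21 argue against a fall of all of them by as much as that measured for GRN and CTSZ. Both genes were picked for their low ratios and neither passed, so their own fall may be smaller than measured. A fall of all lysosomal genes by such a smaller amount is not excluded. BMP7 and PMEPA1 raised the hypothesis that targets of TGF-beta and BMP signalling could be lower too. Over 9 other targets, 1 of them also in the trophectoderm list, the median was -0.039, with 5 below 0 and a camera unadjusted p of 0.48; only 3 of them were above the limit in both channels of all arrays, at a median of -0.0861, too few to test a fall as large as that of BMP7 and PMEPA1. A p over 0.05 with under 60% of the genes below 0 had been set in advance to speak against each hypothesis. The shares have 95% binomial intervals of 23.2% to 65.5% and 21.2% to 86.3%, which reach past 60%, so a smaller or partial fall of lysosomal genes, and any fall of the targets, stay open.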
